A study of Drosophila melanogaster with 2 samples.

How the data were processed

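Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole *Drosophila melanogaster* embryos of mixed sex, aged 0 to 24 hours. The flies carried a transgene for Zfh2, a large zinc finger and homeodomain protein, fused at its C terminus to green fluorescent protein (eGFP). An antibody against GFP was used for the precipitation, per the labels, and chromatin was sheared by sonication to fragments of 200 to 800 bp. There were 2 libraries, labelled biological replicates 1 and 2, in 1 group, so no comparison between groups was possible. Because the fusion was precipitated from whole embryos, each peak is a value over all tissues and all stages of embryogenesis in the collection.

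The deposited files were peak lists, and each list held 10 columns in narrowPeak layout with no header. For the dm6 build and again for the dm3 build there were 4 lists: relaxed calls for replicate 1, relaxed calls for replicate 2, relaxed calls for both replicates pooled, and an optimal list thresholded by the irreproducible discovery rate (IDR), which the submitters derived from the relaxed lists, per the deposited file descriptions. The relaxed lists were made as input for IDR, hold true sites and background together, and end at 30000 calls at most. Calls were made against a control alignment, per the deposited file descriptions, and the control's own values were not used here. The aligner, the peak caller and their versions are not given in the sources used here. Column 7 of the deposited lists holds the caller's signal value, a score with no fixed scale that was used to rank peaks within a list. Column 9 of the deposited lists holds −log10 of a q-value, which takes 1 constant value in each IDR list and so ranks nothing there. Read numbers per library were not used here, so the depth is unknown, and intervals on shares of peaks cover counting error only. Replicate 1 reached the limit of 30000 calls, and replicate 2 did not (29690 on dm6, 27410 on dm3). Because relaxed lists hold background as well as sites, their length says nothing about how many sites a replicate holds.

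All main results used the dm6 IDR list. Summit positions were taken as the start of the interval plus the offset in the last column. Repeated intervals with different summits were kept as separate peaks, of which the dm6 IDR list had 16, and 4 summits lay outside their own interval. Genes, transcripts, transcription start sites (TSS) and exons came from Ensembl release 115, on the same assembly as dm6, with transposable elements left out, which gave 18164 genes on the 6 main arms (2L, 2R, 3L, 3R, 4 and X). A summit was called a promoter summit within 500 bp of a TSS, and otherwise took the first that applied of 5' UTR, 3' UTR, coding exon, noncoding exon, intron and intergenic. A gene counted as carrying a peak when a summit lay in its body or within 1 kb of it. A peak could thus count for more than 1 gene, and its nearest TSS could belong to a neighbour. Coordinates are dm6 and 1-based. No dm3 genome was used, so dm3 lists entered the peak count, the replicate comparison and the distribution over arms only, with arm lengths taken from the span of the calls.

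Replicates were compared by the share of IDR summits inside a relaxed call of each, and by the share of the strongest calls with summits within 200 bp of each other, against 100 random placements on the same arms. Features and clustering were tested by permutation, with summits placed at random on the same arm 1000 times and a two-sided empirical p, for which 0.001998 is the smallest value possible. Weak pooled calls as another background for features were compared with Fisher's exact test. Arms were tested with exact binomial tests against their share of sequence. Gene lists were compared with 10000 random lists of the same size matched on gene length decile (protein-coding genes for protein-coding lists), a permutation of gene labels within deciles, for which 0.0002 is the smallest p possible. Fixed sequence words were sought on both strands in windows of 50 bp on each side of the summit. Their share was divided by the mean share in windows centred 1000 bp away on both sides, and the summit window was tested against the right flank with an exact McNemar test. Windows matched on GC content and arm were drawn as another background and compared with Fisher's exact test. All 6-mers were searched in the same way. Adjusted p-values are Benjamini-Hochberg values over the 7 features, the 6 arms, the 21 lists, the 16 words or all 6-mers, at a threshold of 0.05. Peaks and genes are not biological replicates, list members can be neighbours on a chromosome, and these p-values describe this list of peaks and not the spread between embryos.

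The lists, words, tests and alternatives were chosen before the data were examined, as was the rule for genes named in the text. The rule takes the genes with the TSS nearest to the 20 peaks of highest signal, the 10 genes with the most peaks, up to 4 members of each list with the highest signal and up to 2 members without a peak in alphabetical order, *zfh2* itself, and the 10 most enriched 6-mers. Members were matched by exact symbol and then by a unique synonym, and 5 symbols over all lists found no match and were left out. The lists were neuroblast temporal factors, proneural and neuroblast genes, neuronal differentiation genes, neuronal identity transcription factors, dopamine and serotonin genes, wing hinge and proximodistal patterning genes, apoptosis genes, Hox genes, segmentation genes, Notch pathway genes, glial genes, muscle and mesoderm genes, gut and fat body genes, epidermal and cuticle genes, tracheal genes, germline genes, ecdysone pathway genes, heat shock genes, ribosomal protein genes, odorant and gustatory receptor genes, and transfer RNA genes. Together they held 804 memberships and 770 distinct genes.

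Alternatives covered a stricter peak list, either replicate alone, the dm3 lists, other overlap and promoter definitions, other ways to assign peaks to genes, other matching of random lists, other windows and backgrounds for words, and other neighbour distances. Merged summits, promoter and non-promoter peaks taken separately, the strongest 434 peaks and 7 further gene families were added after the data had been seen. The statistics were tested on simulated lists before use. In 20 simulated lists of 4000 summits with planted promoter peaks, the feature test called all 20, with a mean promoter share of 56.6% where 56.7% had been planted, and it made 0 calls among 140 features with nothing planted. The gene list test called 200 of 200 simulated lists of bound genes and 3 of 200 lists drawn at random. The word test called the planted word in 20 of 20 simulations and made 3 calls among 80 words with nothing planted. The clustering test called 20 of 20 lists with planted neighbours and 2 of 20 without, and the arm test called 20 of 20 with planted peaks on X and 0 of 120 arms without. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.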

Results

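The data describe where the Zfh2-eGFP fusion was found on chromatin of whole embryos over the first 24 hours of development. Zfh2 is known from work on the nervous system and on the proximal parts of wing and leg. The IDR list held 4344 peaks on dm6, with a median width of 400 bp, and they covered 1468265 bp of the main arms. Signal values ran from 64.9 to 2951 with a median of 113. The relaxed lists held 30000 calls for replicate 1, 29690 for replicate 2 and 30000 for the pooled replicates. The dm3 IDR list held 4320 peaks.

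The strongest peaks lay at promoters and in introns of genes with varied functions. The peak of highest signal (3L 19590419 to 19590827) had its summit 97 bp upstream of the TSS of *CG14100*, with a signal of 2951 in the IDR list, 1654 in replicate 1 and 1308 in replicate 2. The next (X 2703679 to 2704094) had its summit 39 bp upstream of *Ugalt*, which encodes a UDP-galactose transporter, with a signal of 2185. The peak with its summit at 2L 481102 had a signal of 1826 and lay in an intron of *ush*, a zinc finger cofactor gene, at position -1414 bp from the nearest TSS, that of *cbt*. At *CG11050* (2L 6612474 to 6612918) the signal was 1710 in an intron, and at *Chro*, which encodes a chromodomain protein of polytene interbands, it was 1430 at a summit 95 bp downstream of the TSS. Of the strongest 20 peaks, 14 lay in promoters and 6 in introns. They had signals from 1080 to 2951, and the lowest rank any of them took was 25 in replicate 1 and 24 in replicate 2. Among the promoters were those of *Shc* (signal 1337), a signalling adaptor, *Atf3* (1315), a bZIP transcription factor, *mRpL41* (1312), a mitochondrial ribosomal protein, and *ph-p* (1196), a Polycomb group gene. By number of peaks in the body or within 1 kb, *lncRNA:CR44357* on X came first with 16, and *CG1677*, which overlaps it, had 14. Both *kirre*, known for myoblast fusion, and *sbb* carried 10, as did *CHES-1-like*. *Tlk*, *Raf* and *shn* carried 9 each, with highest signals of 709.6, 624.9 and 174.7. These counts were not set against gene length, so a high count need not mean a dense locus. The *kirre* gene spans X 2740384 to 3134532, on an arm with 35.3 peaks per Mb.

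The tagged gene was examined first among single loci. *zfh2* (4, 501810 to 540874) carried 0 IDR peaks in its body or within 1 kb. The relaxed lists had 16 calls there in the pooled replicates, 14 in replicate 1 and 25 in replicate 2. The strongest pooled call had a signal of 59.1 and ranked 4832.

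The only contrast in the labels is replicate 1 against replicate 2, and it asks how far the same places were called in both. Of the 4344 IDR summits, 99.1% lay in a call of replicate 1 and 99.3% in a call of replicate 2, and 98.4% lay in calls of both (95% exact interval 98.0 to 98.8%). The IDR list was made from these calls, so this share is high by construction. When as many of the strongest calls as IDR peaks were taken from each replicate, 76.1% of those in replicate 1 had a summit of replicate 2 within 200 bp, against at most 1.77% in random placements. Over lists of 29690 calls each the share was 44.8%, against 8.53% at random. Across the 4276 peaks found in both, the signal of the replicates had a Spearman correlation of 0.64 and a Pearson correlation of 0.72 on the log2 scale. These correlations are across peaks, which are not independent replicates. They also cover only peaks that passed the IDR threshold on these 2 replicates, so they do not measure agreement over all calls.

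**Figure D1:**
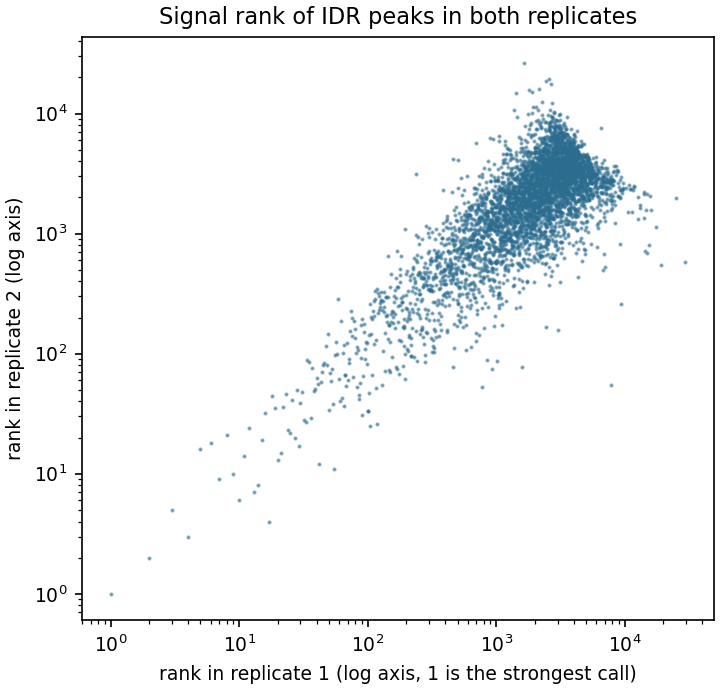
Each point is 1 of the 4276 IDR peaks found in both relaxed lists, with its signal rank in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis (log axes, 1 is the strongest call). The points follow the diagonal with scatter that widens among weaker peaks, and the Spearman correlation across peaks was 0.64.

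Where in genes the peaks fall was asked next. Promoters held 2800 of the 4344 summits, 64.5%, against 13.6% ± 0.522 (SD over 1000 random placements), which is 4.75-fold more (permutation test, adjusted p = 0.0028, from an unadjusted p of 0.001998, the smallest the placements allow). Introns held 1132 summits, 26.1% against 39.6% at random, and intergenic sequence held 330, 7.60% against 27.0%. Coding exons outside promoters held 9 summits, 0.207% against 13.1%, and 3' UTRs held 29, 0.668% against 5.10%. All of these were below random past the threshold (permutation test, adjusted p = 0.0028 for each), as were 5' UTRs with 17 summits, 0.391% against 0.783% (adjusted p = 0.0047). Noncoding exons held 27 summits, 0.622% against 0.825%, and did not pass (permutation test, adjusted p = 0.198). The fall in 5' UTRs was lost in the strongest calls of replicate 1 alone (0.76-fold, permutation test, adjusted p = 0.207), and coding exons lay at 0.0088-fold in the strongest calls of replicate 2 alone against 0.0158-fold in the IDR list. Against weak pooled calls noncoding exons also passed below (0.63-fold, Fisher's exact test, adjusted p = 0.030). Promoter peaks had a median signal of 121 and other peaks one of 101. The share of promoters was 73.3% (95% exact interval 70.6 to 75.9%) among the 1086 strongest peaks and 55.2% (52.1 to 58.1%) among the 1086 weakest.

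**Figure D2:**
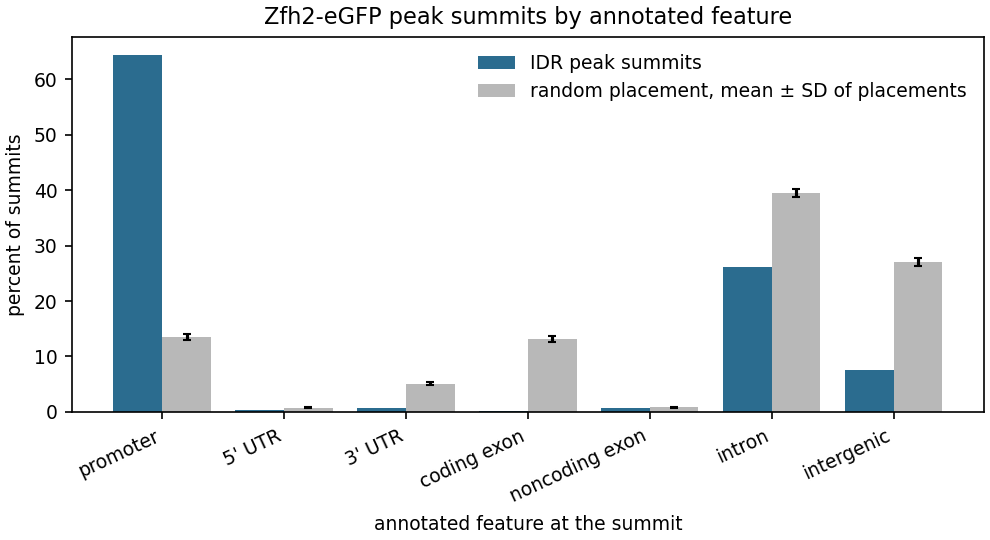
Bars give the percent of summits in each annotated feature for the 4344 IDR peaks (blue) and for random placement on the same arms (grey, mean ± SD of 1000 placements). Promoters hold 64.5% of the peaks and 13.6% of the random positions, and every other class lies below its random share.

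Promoter summits sat just upstream of the start site. Of the 2800 promoter summits, 2307 or 82.4% (95% exact interval 80.9 to 83.8%) lay upstream of the nearest TSS, against 44.7% of random promoter positions. The median position was -70 bp, with quartiles at -145 and -22.8 bp. A total of 1632 summits, 58.3%, lay within 150 bp upstream, against 16.8% at random. The 1544 other summits had a median distance of 1876 bp to the nearest TSS, and 113 of them lay beyond 10 kb (10000 bp).

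**Figure D3:**
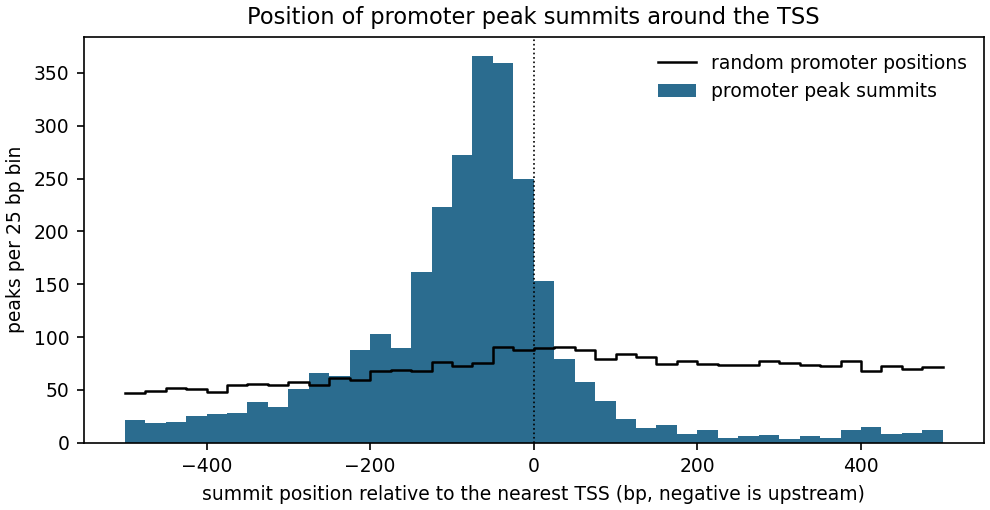
The histogram gives the number of promoter peak summits per 25 bp bin against the distance to the nearest TSS in bp, negative upstream. The line gives random promoter positions scaled to the same number. Summits concentrate just upstream of the TSS, with a median at -70 bp, while the random positions are spread over the window.

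A further question was which groups of genes carry peaks. Of 13945 protein-coding genes on the main arms, 4654 (33.4%) carried a peak in the body or within 1 kb and 3428 (24.6%) carried one at a promoter. Ribosomal protein genes stood out above the rest. A peak lay at 71 of the 85 members, 83.5%, where length-matched random lists had 25.9% ± 4.65 (SD over lists; permutation test, adjusted p = 0.0014, from an unadjusted p of 0.0002, the smallest the lists allow), and 67 of the 85 carried a peak at a promoter. Examples were *RpL34b* (3R, signal 610.5, summit 83 bp upstream), *RpS27* (3R, 600.7), *RpL7* (2L, 564.2) and *RpL23A* (3L, 480.5), while *RpL10Aa* and *RpL21* had no peak. No other list lay above its random lists past the threshold. Heat shock genes carried peaks at 6 of 13 members, with *Hsp27* at 421.3 and *Hsp83*, which encodes Hsp90, at 209.5 (adjusted permutation p = 0.606). Apoptosis genes had 6 of 12, among them *Dark* at 247.1 and *Diap1* at 236.3 (adjusted permutation p = 0.770), and germline genes had 6 of 12, among them *bgcn* at 185.6 and *Sxl* at 154.8 (adjusted permutation p = 0.940). The *Dark* summit lay past the 3' end of *Dark*, within *asRNA:CR44390* and 95 bp from a TSS that is not one of *Dark*. Notch pathway genes had 6 of 16, with *mam* at 285.9, *neur* at 218.4 and *N* at 194.0 (adjusted permutation p = 0.836). The summits named for *Diap1* and *mam* lay in no call of replicate 1, and had signals of 96.9 and 165.9 in replicate 2. Ecdysone pathway genes had 8 of 17, with *Hr3* at 527.7, *Hr4* at 296.9 and *EcR* at 267.9, each in an intron (adjusted permutation p = 1).

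Of the 21 lists, 6 lay below their random lists past the threshold. Segmentation genes had 0 of 20 members with a peak where 7.86 were expected, and *Kr* and *en* were among them (adjusted permutation p = 0.0014). Odorant and gustatory receptor genes had 5 of 119 where 35.1 were expected (adjusted permutation p = 0.0014). Wing hinge and proximodistal patterning genes had 7 of 34 where 16.5 were expected (adjusted permutation p = 0.0094), and *hth* (signal 120.2) and *tup* (97.7) were the strongest of them, while *B-H1* and *B-H2* had none. The *tup* summit lay past the 3' end of *tup*, 74 bp upstream of the TSS of another gene. Neuronal identity transcription factors had 6 of 29 where 13.8 were expected (adjusted permutation p = 0.019), with *otp* at 341.1, *fru* at 280.2 and *zfh1* at 259.6, and *Lim1* and *Lim3* without a peak. Neuronal differentiation genes had 3 of 19 where 9.62 were expected (adjusted permutation p = 0.017), with *elav*, the pan-neuronal RNA-binding protein gene, at 476.8 and *Appl* and *Fas2* without. Epidermal and cuticle genes had 2 of 16 where 7.37 were expected (adjusted permutation p = 0.031), and these were *grh* at 142.8 and *Cht7* at 125.8. The calls for wing hinge, neuronal identity, neuronal differentiation and epidermal genes were lost against random lists that were not matched on length (adjusted permutation p = 0.473, 0.481, 0.473 and 0.473) and when peaks were given to the nearest TSS (0.314, 0.260, 0.098 and 0.958). Those lists were also lost with random lists matched on length plus gaps (adjusted permutation p = 0.428 for wing hinge, 0.470 for neuronal identity, 0.428 for neuronal differentiation and 0.428 for epidermal genes). In the 2172 strongest peaks the calls for neuronal identity, neuronal differentiation and epidermal genes ended (adjusted permutation p = 0.078, 0.056 and 0.365), at folds of 0.34, 0.17 and 0.43 against 0.43, 0.31 and 0.27 in the full list. With a margin of 5 kb those for neuronal differentiation and epidermal genes ended (0.57-fold and 0.71-fold, adjusted permutation p = 0.056 and 0.319), and with promoter peaks alone that for epidermal genes (0.20-fold, adjusted p = 0.121). The wing hinge call held in the 2172 strongest peaks (0.097-fold, adjusted permutation p = 0.0014). With promoter peaks alone, wing hinge genes had 0 of 34 and neuronal identity genes 0 of 29 (adjusted permutation p = 0.0010 for each). The segmentation call was lost only with peaks given to the nearest TSS (adjusted permutation p = 0.369), and in the strongest calls of replicate 1 alone its fold was 0.13.

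The other lists did not pass, apart from the settings named here. Neuroblast temporal factors had 5 of 21 members with a peak (adjusted permutation p = 0.137), among them *grh* and *hth*, and 0 of 21 with one at a promoter, which is below random when promoter peaks alone are counted (adjusted permutation p = 0.0059). Proneural and neuroblast genes had 3 of 18, which were *numb* at 217.8, *brat* at 196.1 and *insc* at 97.1 (adjusted permutation p = 0.152), and the list passed below random with a margin of 5 kb (0.40-fold, adjusted p = 0.023). The *insc* summit lay in the body of *insc*, 85 bp upstream of the TSS of another gene. Hox genes had 3 of 11, which were *bcd* at 117.7, *Antp* at 108.9 and *Ubx* at 102.7 (0.59-fold, adjusted permutation p = 0.546), and lay at 0.98-fold in the strongest calls of replicate 2 alone. Dopamine and serotonin genes had 3 of 12, with *Pu* at 124.0 and *Ddc* without a peak (adjusted permutation p = 0.546). The *Pu* summit lay past the 3' end of *Pu* and 30 bp upstream of the TSS of *tud*, a germline list member counted with the same peak. Tracheal genes had 2 of 12, which were *trh* at 101.7 and *bnl* at 85.7 (0.34-fold, adjusted permutation p = 0.109), and passed below random in the strongest calls of replicate 1 alone (0.17-fold, adjusted p = 0.028). Glial genes had 5 of 14, with *moody*, a receptor gene of the blood-brain barrier, at 647.8 (adjusted permutation p = 0.777). Muscle and mesoderm genes had 7 of 20, with *sls* at 322.8 and *Mef2* at 116.9 (adjusted permutation p = 0.606), and gut and fat body genes had 5 of 14, with *fkh* at 187.0 (0.79-fold, adjusted permutation p = 0.777) and 0.47-fold in the strongest calls of replicate 1 alone. Transfer RNA genes had 24 of 290 (adjusted permutation p = 0.546), and they passed below random against unmatched lists (0.29-fold, adjusted p = 0.0014), lists matched on length plus gaps (0.35-fold, adjusted p = 0.0014) and with a margin of 5 kb (0.63-fold, adjusted p = 0.0010).

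**Figure D4:**
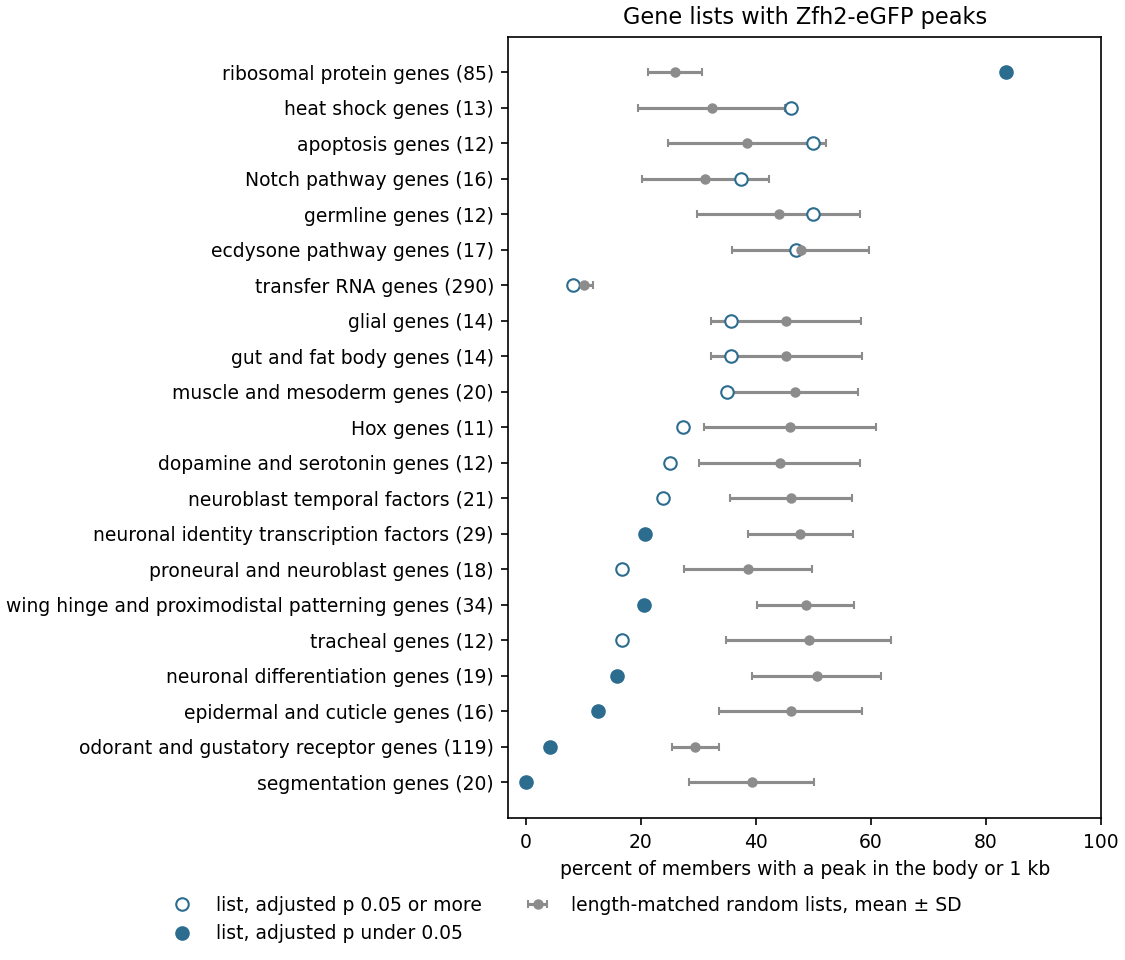
Blue circles give the percent of members of each gene list (number of members in brackets) with a peak in the gene body or within 1 kb, filled where the adjusted p is under 0.05. Grey points with bars give length-matched random lists (mean ± SD of 10000 lists). Ribosomal protein genes at 83.5% lie far above their random lists, and segmentation genes at 0% lie below theirs.

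Which sequence words mark the summits was asked with words fixed beforehand. TATCGATA, the DNA replication-related element known to be bound by Dref, was present in 174 of 4344 summit windows, 4.01%, against 0.414% of flanking windows (9.67-fold, exact McNemar test, adjusted p = 2.7e-34). GGTCACAC, part of the core promoter motif bound by M1BP, was present in 93 windows, 2.14% against 0.265% (8.09-fold, exact test, adjusted p = 8.0e-18), with 4.79-fold in the strongest calls of replicate 2 alone and 4.125-fold in the 2172 strongest peaks. TGTTTAC, a forkhead word, was 1.56-fold higher (3.48% against 2.22%, exact test, adjusted p = 0.00073). The words CACACACA (0.38-fold, exact test, adjusted p = 4.1e-09), GAGAGAG (0.54-fold, adjusted p = 0.00013), CAGGTG (0.68-fold, adjusted p = 0.00073) and CAGGTAG (0.66-fold, adjusted p = 0.042) were less frequent at summits than in flanks. The first of these is a dinucleotide repeat, GAGAGAG is a word of GAGA factor, and CAGGTAG is the word of Zelda. TAATTA, a core word of many homeodomains, was present in 6.98% of summits and 6.04% of flanks (1.15-fold, exact test, adjusted p = 0.160). TAATTA passed the threshold with windows of 100 bp on each side (1.33-fold) and in the strongest calls of replicate 2 alone (1.44-fold), and it lay at 0.85-fold against windows matched on GC content (exact test, adjusted p = 0.064). The falls of CACACACA and GAGAGAG did not pass in the strongest calls of replicate 1 alone (0.69-fold and 0.86-fold, exact tests, adjusted p = 0.063 and 0.337), and that of GAGAGAG did not with windows of 25 bp on each side (exact test, adjusted p = 0.144) or at promoter peaks alone (0.148). The fall of CAGGTAG did not pass in either replicate alone (exact tests, adjusted p = 0.180 for replicate 1 and 0.408 for replicate 2), in the 2172 strongest peaks (0.192) or with windows of 100 bp on each side (0.194). Against GC-matched windows GAGAGAG, CAGGTG and CAGGTAG lay at 1.33-fold, 1.07-fold and 1.17-fold and did not pass, while CAGCTG (2.09-fold, exact test, adjusted p = 5.1e-11) and GATAAG (1.44-fold, adjusted p = 0.00051) were enriched and ATTTGCAT was depleted (0.61-fold, adjusted p = 0.013). Summit windows were 37.8% GC and flanks 43.7%. The remaining words, CAATTA, TTAATTAA, ATTTGCAT, ATAAATCA, CAGCTG, CACGTG, GATAAG and TGACTCA, did not pass against flanks, with folds from 0.85 to 1.54. Of these, CAATTA, TTAATTAA and GATAAG passed with windows of 100 bp on each side (1.16, 1.40 and 1.11-fold), CAATTA in the 2172 strongest peaks (1.24-fold) and in the strongest calls of replicate 2 alone (1.202-fold), and GATAAG at promoter peaks alone (1.24-fold).

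The search over all 6-mers found 450 enriched and 693 depleted past the threshold. These counts are against flanks, which were 43.7% GC where summit windows were 37.8%, so base composition can enter them. In the strongest 434 peaks, 91 words were enriched over flanks and 1 over GC-matched windows. The highest folds belonged to CGATAG (10.8% against 2.39%, 4.53-fold), TATCGA (3.51-fold) and ATCGAT (3.18-fold), which overlap the replication-related element, followed by ACTAGT (2.83-fold), ACACTG (2.76-fold), ACTATC (2.69-fold), ACAGTG (2.49-fold), CGATAC (2.40-fold), CCGATA (2.36-fold) and ACCCTA (2.32-fold). The TATCGATA and GGTCACAC words belonged to promoter peaks. At 2800 promoter summits their folds were 21 and 12, and at 1544 other summits they were 0.60 and 0.75 and did not pass (exact McNemar tests, adjusted p = 0.972 and 1). No promoters without a peak served as background, so the folds at promoters do not tell promoters with a peak from promoters in general. A 6-mer search at the other summits did find words enriched over flanks, among them ACAGTG (12.2% against 5.02%, 2.43-fold, exact McNemar test, adjusted p = 2.5e-11). Within the 434 strongest peaks TATCGATA did not pass (2-fold, exact McNemar test, adjusted p = 0.841), nor did TGTTTAC and CAGGTG, and neither of the latter passed at non-promoter peaks.

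**Figure D5:**
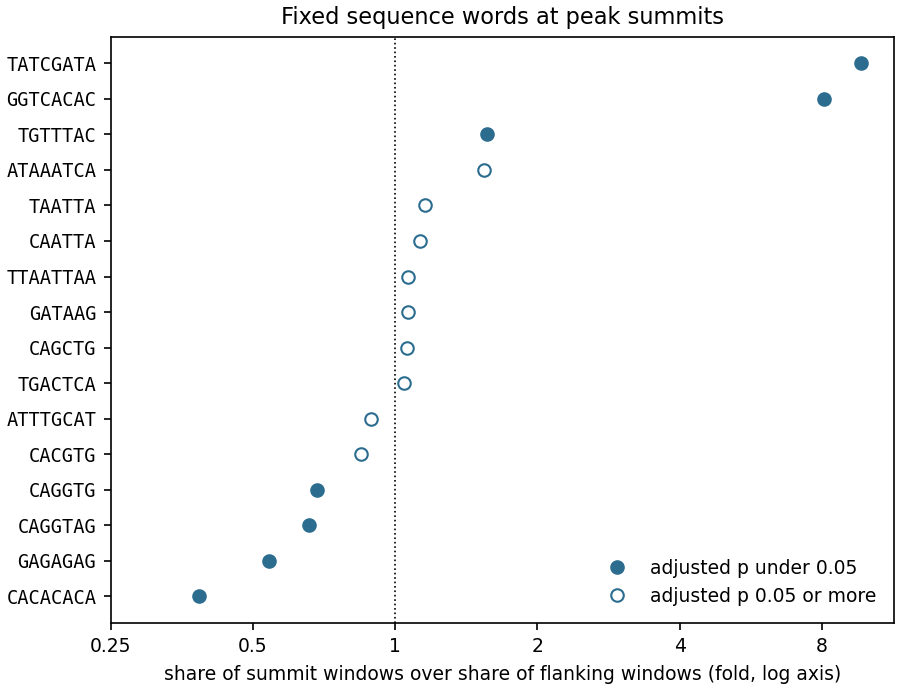
Points give the share of summit windows over the share of flanking windows for each of the 16 fixed words, on a log axis, filled where the adjusted p is under 0.05. TATCGATA at 9.67-fold and GGTCACAC at 8.09-fold stand apart from the others, and CACACACA is lowest at 0.38-fold.

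Peaks lay on all 6 arms, and the density was lowest on chromosome 4. Chromosome 4, a small and mostly heterochromatic chromosome that carries *zfh2*, had 24 peaks, 17.8 per Mb against 32.4 over all arms, which is 0.55-fold (95% exact interval 0.35 to 0.82; exact binomial test, adjusted p = 0.010), and 0.32-fold in the 2172 strongest peaks. Arm 3L had 835 peaks (0.92-fold, exact binomial test, adjusted p = 0.012) and X had 830 (1.09-fold, adjusted p = 0.018). Arms 2L, 2R and 3R, at 1.03-fold, 1.04-fold and 0.98-fold, did not pass. The call on X was lost in the 2172 strongest peaks (exact binomial test, adjusted p = 0.201), and the calls on 3L and X were lost in the dm3 list (adjusted p = 0.095 and 0.535), in which 2R passed (1.11-fold, adjusted p = 0.0052).

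Peaks also lay close together. A neighbouring summit within 5 kb was found for 57.6% of summits, against 27.9% ± 0.889 (SD over placements) at random (2.07-fold, permutation p = 0.001998, the smallest possible). Against draws from the pooled relaxed calls in place of random positions, the expected share was 41.7% (1.38-fold, same p). Promoters held 64.5% of the summits, and no placement matched on promoters was run. Whether the spacing of promoters alone gives the excess was therefore not tested. With summits within 500 bp merged into 1 site, a change made after the data had been seen, 4068 sites remained and 51.6% had a neighbour.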

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

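The dm3 lists hold calls on sequences outside the 6 main arms. The IDR peaks among them entered the dm3 peak count and the share of IDR peaks in both replicate lists. These calls entered no test of arms, features, genes or words. There was no control sample here to set them against, so they stand out only by lying above the 3 calls that a count of 0 allows. The pooled relaxed list for dm3 had 50 of its 30000 calls on heterochromatic, unplaced and mitochondrial sequences. The 3L heterochromatin had 19 of them, 3R heterochromatin 9 and 2R heterochromatin 7. Replicate 1 had 38 such calls and replicate 2 had 102. The dm3 IDR list held 2 peaks there, 1 each on the heterochromatic parts of 3L and 3R. The dm6 lists hold calls on the 6 main arms alone. These sequences were not traced between the builds, and no explanation was tested for the calls on them.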

How the results depend on the processing

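Of 433 values recomputed under an alternative, 302 kept their direction and their side of the threshold, 37 kept the direction and lost the call, 19 kept the direction and gained one, 56 turned, and 19 without a test or counts moved. The splits into promoter and non-promoter peaks, the strongest 434 peaks and the merged summits were chosen after the data had been seen. The excess at promoters (3.13 to 7.32-fold), the clustering (35.9 to 74.3% of summits), the ribosomal protein excess (1.99 to 4.68-fold) and the low density on chromosome 4 (0.32-fold in the strongest 2172 peaks to 0.59-fold) passed in every alternative run for them. Leave-one-out values of the replicate comparison cannot exist, since it needs both libraries. Only the restriction to the strongest IDR peaks changed the number of peaks by over 1.5 times, to 2172, by construction. The depth of the libraries is unknown, and the number of members limits the short lists, where 1 gene moves the share by several percent. Except where a setting takes fewer peaks, the cause was not tested.

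The share of IDR peaks in both replicate lists was 99.7% with 1 bp of overlap and 84.2% with 50% reciprocal overlap. The share of the strongest calls matched between replicates was 69.8% within 100 bp, 77.8% within 500 bp, 77.3% with 2172 calls each and 68.2% with 2 times as many. Among arms that did not pass, the strongest 2172 peaks gave 0.96-fold for 2R and 1.06-fold for 3R, and the dm3 list gave 0.95-fold for 2L and 1.01-fold for 3R, while 2R passed there at 1.11-fold. Without replicates 1 and 2 in turn, 3R ranged from 0.991 to 1.01-fold.

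The number of lists below random was 6, and it was 3 in the strongest 2172 peaks, 1 by nearest TSS, 3 with unmatched random lists and 3 with lists matched on length plus gaps. A list that turned passed neither in that setting nor in the analysis reported, but transfer RNA genes passed below random in other settings (0.29-fold with unmatched lists, 0.35-fold with lists matched on length plus gaps and 0.63-fold with a margin of 5 kb). The strongest 2172 peaks gave 1.18-fold for ecdysone, 0.91-fold for germline and 1.08-fold for transfer RNA genes. Promoter peaks alone gave 0.88-fold for apoptosis and 1.07-fold for transfer RNA genes. The nearest TSS gave 1.16-fold for muscle, 1.09-fold for gut and 1.15-fold for transfer RNA genes, and a margin of 5 kb gave 1.39-fold for glial and 1.14-fold for ecdysone genes. Unmatched lists gave 1.07-fold for glial, 1.05-fold for muscle, 1.07-fold for gut and 1.41-fold for ecdysone genes. Lists matched on length plus gaps gave 1.08, 1.04, 1.12 and 1.37-fold for the same lists. Leaving out either replicate gave 0.999 to 1.198-fold for Notch, 0.974 to 1.11-fold for ecdysone and 0.954 to 1.13-fold for germline genes.

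The numbers of fixed words enriched and depleted were 3 and 4. They were 5 and 2 against GC-matched windows, 0 and 2 in non-promoter peaks, and 7 words were enriched with windows of 100 bp on each side. The strongest 434 peaks had 0 enriched. Leaving out either replicate gave 3 to 5 enriched and 1 to 3 depleted. Against GC-matched windows the folds were 0.85 for TAATTA, 0.78 for TTAATTAA, 1.17 for CAGGTAG, 1.07 for CAGGTG, 1.11 for CACGTG, 1.33 for GAGAGAG, 0.67 for ATAAATCA and 0.88 for CAATTA. None of these passed, so the depletion of CAGGTAG, CAGGTG and GAGAGAG at summits rests on a comparison with flanks of higher GC content. The strongest 2172 peaks gave 1.26 for ATTTGCAT, 0.84 for CAGCTG, 0.98 for GATAAG and 0.94 for TGACTCA. The strongest 434 peaks gave 1.27 for ATTTGCAT, 0.29 for CAGCTG (exact test, adjusted p = 0.027), 0.83 for GATAAG and 0.40 for GGTCACAC. Non-promoter peaks gave 1.24 for ATTTGCAT, 1 for TTAATTAA, 1.16 for CAGGTAG, 0.95 for CAGCTG, 0.79 for GATAAG, 0.60 for TATCGATA and 0.75 for GGTCACAC. Windows of 25 bp on each side gave 0.97 for CAGCTG. Leaving out either replicate gave 0.98 to 1.44 for TAATTA, 1 to 1.02 for ATTTGCAT, 0.94 to 1.06 for CAGCTG, 0.80 to 1.09 for CACGTG and 0.96 to 1.202 for CAATTA.

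No paired analysis was possible because there is a single group of 2 libraries.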

Other observations

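The tests below were chosen after the main results had been seen. Those on transcription, word strength, weak-call words against flanks, chromosome 4 gene density, head-to-head pairs and added gene families were written down before their own deciding values were known. Those on base composition and chromosome 4 coverage were written down after, and those on the strongest 434 peaks, gene lists at weak calls and GC-matched weak-call windows were not written down beforehand. Other gene families resembled the ribosomal protein genes only in part. Mitochondrial ribosomal protein genes carried a promoter peak at 39 of 73 members, where 11.2 were expected in length-matched lists (permutation test, adjusted p = 0.00047), led by *mRpL41*, *mRpS23* and *mRpS10* with signals of 1312, 1157 and 1068. The signal given for *mRpS23* matches that of a 2L peak with its summit 119 bp upstream of its nearest TSS, that of *CenG1A*. Proteasome subunits had 16 of 32 where 7.10 were expected (adjusted permutation p = 0.0017), with *Rpn5* at 413.3. Genes of tRNA synthetases had 13 of 32 (adjusted permutation p = 0.236) and Mediator subunits 9 of 25 (adjusted permutation p = 0.189), and neither passed. Hence 2 of 4 groups taken as used by most cells lay above random, which leaves open the hypothesis that such groups carry promoter peaks in general. Families taken as used by few cells lay below length-matched random lists in 3 of 3 cases, as the hypothesis that restricted families are left out predicts. Use across cells was not measured in these data, and members of a family can be neighbours on a chromosome. Cytochrome P450 genes had 4 of 81 (adjusted permutation p = 0.00047), cuticular protein genes 1 of 104, *Lcp9* (adjusted p = 0.00047), and odorant binding protein genes 1 of 49, *Obp83g* (adjusted p = 0.010).

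Promoters shared by a pair of divergent genes carried peaks more often than single ones. Of 1691 head-to-head pairs with start sites at most 500 bp apart, 825 or 48.8% (95% exact interval 46.4 to 51.2%) had a peak in a 1 kb window. The share was 14.5% (13.8 to 15.2%) of 10563 single promoters, a ratio of 3.37 (Fisher's exact test, p = 2.7e-200). If the 2 promoters of a pair were independent, 26.9% of pairs would carry a peak, and the observed share was 1.82 times that. That expected share takes paired promoters to carry peaks at the rate of single ones. Gene class was not matched between pairs and single promoters, so a difference in class cannot be told apart from sharing.

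The strongest 434 peaks differed in sequence from the rest. TATCGATA lay in 5 of their 434 windows, 1.15% (95% exact interval 0.38 to 2.67%), against 4.32% of the other 3910 (Fisher's exact test, adjusted p = 0.0035), and GGTCACAC lay in 1 window, 0.23% against 2.35% (adjusted p = 0.0066). CAGCTG was also less frequent, 1.84% against 5.98% (Fisher's exact test, adjusted p = 0.0015), and the other 13 fixed words did not pass. Neither TATCGATA nor GGTCACAC occurred in the windows of the strongest 20 peaks. With shares of 4.01% and 2.14% over all summit windows, 20 windows are too few to show a difference. The windows of the strongest 434 peaks were also poorer in GC, 34.6% against 38.1% in the other peaks. A search of all 6-mers found 91 enriched over flanks, and against GC-matched windows it found 1, AGCACT, at 4.50-fold (Fisher's exact test, adjusted p = 0.033).

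The TATCGATA and GGTCACAC words at promoter summits are known from housekeeping promoters, not from Zfh2. The tables argue against base composition as the cause, since the fold of TATCGATA was 14.5 against windows matched on GC content and arm (Fisher's exact test, adjusted p = 1.9e-37). Those windows were not restricted to promoters. Among peaks past the IDR threshold, 3.50% of the 1086 strongest and 4.14% of the 1086 weakest held TATCGATA. The ratio was 0.84 (95% interval 0.55 to 1.29), an interval below the 1.5 set beforehand. Promoter share also differed between the 2 sets, 73.3% against 55.2%, and was not held fixed. The ratio therefore says nothing on signal and word outside these peaks or at promoters alone. Precipitation that follows transcription regardless of Zfh2 stays open, since a control precipitation was not analysed here, and the median signal of the 72 promoter peaks at ribosomal protein genes, 1.25 times that of 2728 others, decides nothing on a score with no fixed scale and among peaks past the IDR threshold alone. The design gives no group for a biological explanation of these words and none was tested for them, and Zfh2 may reach these promoters with other proteins or the signal may be nonspecific.

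Of 114 distinct genes in 6 developmental lists (temporal, proneural, neuronal identity, wing hinge, Hox and segmentation), pooled after their counts had been seen and so given without a test, 21 carried a peak in the body or within 1 kb, where length-matched lists had 51.8 and unmatched ones 38.0. A promoter peak lay at 3 of them, *bcd*, *numb* and *brat*, where these lists had 33.6 and 28.0 and lists matched on length plus gaps had 22.6. One candidate explanation is that sites used in a small share of cells stayed below the IDR threshold. Among 18316 weaker non-promoter calls, TAATTA lay at 0.76-fold against flanks and 1.02-fold against GC-matched windows, so as a set they held no excess. Such a call lay at 62 of the 114 genes, where length-matched lists had 82.0. All 6 lists lay below random (0.56 to 0.85-fold) and none passed the threshold (permutation tests, adjusted p from 0.106 to 0.377). Neither result decides on the explanation, because these calls hold true sites and background together, and a minority of sites could go unseen. TAATTA may also not stand for Zfh2 sites. Of all 21 lists at these weaker non-promoter calls, only ribosomal protein genes passed, and they lay above random. Such a call lay at 44 of 85 members where 25.6 were expected (1.72-fold, permutation test, adjusted p = 0.0042). What this means for their excess in the IDR list was not tested. Whether weak calls mark open chromatin stays open: CAGGTAG, GAGAGAG and GATAAG, 3 of 3, had a higher fold than TAATTA, but against flanks TAATTA was itself depleted, and against GC-matched windows GAGAGAG (1.26-fold, Fisher's exact test, adjusted p = 0.042) and GATAAG (1.16-fold, adjusted p = 0.023) passed while CAGGTAG (1.03-fold) did not, with no test between words.

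Chromosome 4 had few peaks for its length, 0.55-fold. The share of its protein-coding genes with a promoter peak was 20 of 80, against 24.6% of 13865 on the other arms, a ratio of 1.02 (Fisher's exact test, p = 0.897), and it had 59.3 genes per Mb against 105 elsewhere. These values are consistent with gene density as the source. Poor coverage by mapped reads cannot be told apart from it, because the relaxed calls on chromosome 4 lay at 0.91-fold in the pooled list but at 0.63-fold in replicate 1 and 1.298-fold in replicate 2.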
